A study of Homo sapiens with 8 samples.

How the data were processed

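RNA was measured by sequencing in 8 libraries of HCT116, an established human colon cancer cell line. According to the labels, 4 libraries came from parental cells with wild-type GNAS and 4 from a derivative made by CRISPR-Cas9 editing that carries R201C on one GNAS allele, written here as GNAS R201C/+. Cells of both groups were grown in the same medium with serum, total RNA was purified on spin columns, and libraries were made with a directional kit, per the labels' protocols. The replicate numbers run from 1 to 4 in each group. The labels do not say whether replicates were separate cultures or whether the derivative is a single clone, so p-values measure only the spread between these libraries, which may be technical.

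The deposited table holds raw read counts per gene, whole numbers for 60609 Ensembl gene identifiers in 8 columns, 1 per library, and every column was used. Per the submitters' processing notes, the authors used bcl2fastq, Trimmomatic, STAR, featureCounts and DESeq2 with the GRCh38.p12 genome build, and no version is named for any of these tools. The annotation release, the strand setting of the counting and any filter on multiply mapped reads are not given in the sources used here. Reads of a gene and of a gene on the opposite strand over the same bases therefore could not be told apart with certainty, and genes with near-identical copies are reported as uncertain.

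Gene names, positions, exonic length and GC content were taken from the GENCODE 29 annotation of GRCh38, matched on the gene identifier without its version. That annotation held 58457 of the identifiers, a table of gene names held another 2088, and 64 had no match. Coordinates are 1-based. The codon of R201 was located in the annotated transcript and its sequence is the reference sequence. The mutant allele's share of GNAS reads was not analysed here, because counts per gene carry no allele.

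Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the filterByExpr rule with its minimum count of 10 and minimum total count of 15, which left 15751 of the 32806 genes with any read. Library sizes were scaled with TMM factors, a negative binomial model with group as its only term was fitted with robust estimation, and the quasi-likelihood F test was applied with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. This is an approximation, which can be too small where a change is large and a group has few reads. Expression levels are CPM, counts scaled to a common TMM-adjusted library size, given as mean ± SD over the 4 libraries of a group. Fold changes are GNAS R201C/+ relative to parental.

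Before the data were examined, 25 gene lists were written down: cAMP and CREB response genes, cAMP phosphodiesterases, cAMP pathway components, mucins and secretory lineage genes, Wnt and beta-catenin targets, ERK pathway output, YAP and TEAD targets, enterocyte and colonocyte differentiation genes, epithelial junction genes, mesenchymal and EMT genes, proliferation genes, p53 targets, glycolysis and hypoxia response genes, cholesterol synthesis genes, unfolded protein response and ATF4 targets, interferon response genes, MHC class I presentation genes, NF-kB and inflammatory genes, intestinal fluid and ion transport genes, neuroendocrine genes, leukocyte, fibroblast and endothelial markers, mitochondrially encoded genes, and neighbours of GNAS. Each list with at least 5 tested genes, and each of 23 chromosomes, was tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The test was repeated with the correlation estimated from the data, which also limits it to the residual degrees of freedom, and with fry.

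The rule for naming genes was also fixed then. It takes GNAS and GNAS-AS1. It takes the 10 rising and the 10 falling genes with the largest change among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. From each list it takes up to 4 called members with the smallest adjusted p, or, where none was called, up to 2 members given as values. Undetected members of a list could be named as such. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so.

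The alternatives were DESeq2 1.42.0, limma-voom, other scalings (DESeq2 size factors, upper quartile, library totals only), no filter on low counts, a filter of 1 CPM in 4 libraries, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. The pseudocount alternative did not apply, since the values are counts. Logged values, used for the principal components, had a prior count of 2. The edgeR calls, the camera tests, the permutation of neighbouring genes and the removal of a GC trend were tested on simulated data before use. The fry test, the outlier test of single libraries and the binomial and bootstrap intervals were not. In simulated libraries drawn from the real means and library sizes for this comparison, with 15505 genes tested, 72% of genes changed by 0.2 on the log2 scale were recovered. The share was 85.7% at 0.5 and 100% at 1 and at 2, and 3 of 179 calls were false. Only 49 or 50 changed genes of each size were tested there, against 7577 calls in the real data, and each gene's spread followed a fitted trend. These shares may therefore not carry over to the real data. The simulated gene lists held genes drawn independently, so they do not test how camera treats correlated genes. Figures were drawn with matplotlib 3.10.9.

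Total counts were between 42584988 and 50986733 per library. At these depths a gene with no read in a library could have a level of up to 0.0588 to 0.0704 CPM, the level of 3 counts. Such limits and the 95% interval given for PDE4D cover counting error only, since reads without molecular identifiers are not independent molecules. Many genes of the major histocompatibility region and some genes that every cell uses are listed at or near 0 in all 8 libraries. A count of 0 in this table is therefore given only as listed, and gene lists may have lost members this way.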

Results

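Gene expression was profiled by RNA sequencing in parental HCT116 cells, a human colon cancer line, and in a derivative edited to carry the R201C substitution on one allele of GNAS. GNAS encodes the stimulatory G protein alpha subunit, which activates adenylyl cyclase and raises cyclic AMP (cAMP), and R201C is a known activating change. There were 4 libraries per group. The parental libraries held 50986733, 45713506, 42951435 and 42584988 counts for replicates 1 to 4, and the GNAS R201C/+ libraries held 46880604, 45796887, 47459551 and 48768360. Between 24429 and 25079 genes had at least 1 read in a library, and mitochondrial genes took 5.34% to 5.82% of counts. Replicates of a group differed by more than sampling noise in every pairing, so no library was counted as a duplicate. This does not show that replicates came from separate cultures.

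The comparison asked which genes differ in level between the edited and the parental cells. The phosphodiesterase gene PDE4D, whose product breaks down cAMP, went from nearly undetected to 97.5 ± 2.38 CPM (SD, n = 4) in GNAS R201C/+ cells. The mesodermal transcription factor gene TCF21 rose 21.5-fold and the keratin gene KRT7 rose 6.22-fold, while the adhesion receptor gene ADGRF1 fell 35.4-fold and 8 of 9 tested HOXB genes, a family picked after its values were seen, fell. Genes that respond to cAMP and CREB rose as a group, with 15 of 24 tested members higher. Most other changes were small: 7577 of 15751 tested genes were called, 3796 higher and 3781 lower, with a median size of 1.14-fold, and 242 changed at least 2-fold, 132 higher and 110 lower.

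**Figure D1:**
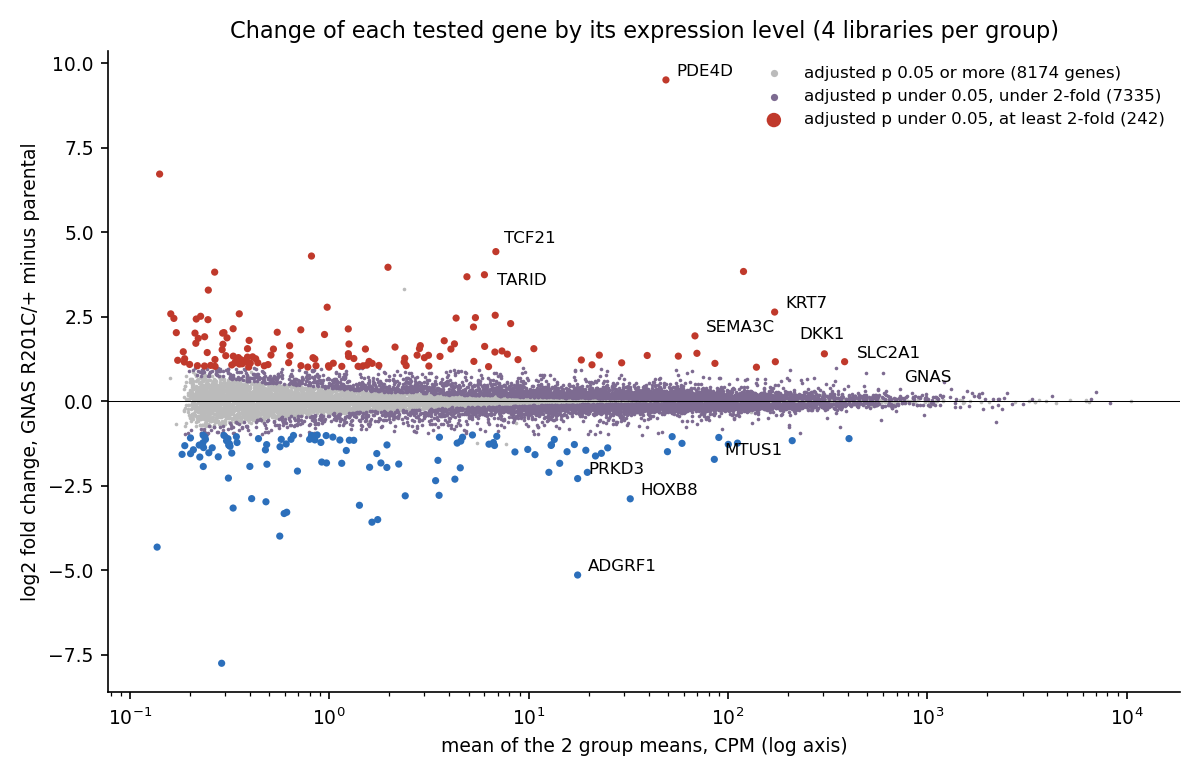
Log2 fold change (vertical axis, GNAS R201C/+ minus parental) of each of 15751 tested genes against its mean level in CPM (horizontal log axis), with called genes that changed at least 2-fold in red (higher) and blue (lower). PDE4D stands alone at 9.51, and most called genes lie close to 0.

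The edited gene was read first. GNAS (ENSG00000087460.25, GRCh38 chromosome 20, 58839718 to 58911192, plus strand) was at 677 ± 16.8 CPM in parental and 711 ± 13.2 CPM in GNAS R201C/+ libraries. The log2 fold change was 0.07 with a standard error of 0.02 (edgeR adjusted p = 0.00412), a 1.05-fold difference, and single libraries of the groups overlapped. Total GNAS reads thus differed little and say nothing about the share of the mutant allele. The R201 codon lies in exon 8 of 13 of transcript ENST00000371085.7, at chromosome 20 positions 58909365 to 58909367, within the coding sequence. Its reference codon is CGT, in the coding context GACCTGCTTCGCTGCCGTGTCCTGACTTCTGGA. The antisense gene GNAS-AS1, on the minus strand of the same locus, had 0 to 4 reads per library and was not tested. Of 14 tested genes near GNAS, 4 rose, 3 fell and 7 did not pass, and the list did not move as a whole (camera adjusted p = 0.595). Its median log2 change was -0.01, its mean 0.14 and its test pointed up. Among these neighbours PMEPA1, a regulator of TGF-beta signalling, rose from 1.06 ± 0.122 to 3.22 ± 0.572 CPM, and the lysosomal protease gene CTSZ rose by 0.17 and TFAP2C by 0.27 on the log2 scale. RAE1, a nuclear export factor gene, fell by 0.11.

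Among the 10 genes with the largest rise, PDE4D (ENSG00000113448.19, chromosome 5, 58969038 to 60522120) came first. Parental libraries held 24 PDE4D reads in all and GNAS R201C/+ libraries 18372, a ratio of 742 after allowing for library size, with an exact 95% binomial counting interval of 498 to 1158. Its log2 fold change was 9.51 (edgeR adjusted p = 8.43e-50). The standard error of 0.07 derived from F is too small here, because the counting interval alone is wider than it allows. KRT7, a keratin of simple epithelia on chromosome 12, went from 47.5 ± 2.13 to 295 ± 24.6 CPM. TCF21 rose from 0.595 ± 0.222 to 13.1 ± 0.397 CPM, and TARID, an antisense gene over it, rose from 0.835 ± 0.105 to 11.2 ± 0.474 CPM. These genes share 1383 exonic bases on opposite strands, so their reads may be mixed. KRT81 rose by 2.54 on the log2 scale and is uncertain, because KRT83 and KRT86 are near-identical copies. HPD, an enzyme of tyrosine breakdown, rose 5.54-fold. PRKAA2, a catalytic subunit of AMP-activated kinase, rose 4.91-fold, the basement membrane collagen gene COL4A6 rose 4.57-fold, and the secreted guidance factor gene SEMA3C rose 3.81-fold.

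Among the 10 genes with the largest fall, ADGRF1 (ENSG00000153292.16, chromosome 6, 46997703 to 47042363) went from 34.2 ± 1.34 to 0.967 ± 0.147 CPM, a log2 change of -5.14 (edgeR adjusted p = 7.30e-41). Its standard error derived from F, 0.07, is likely too small, since GNAS R201C/+ libraries held only 40 to 55 ADGRF1 reads each. HOXB8 (chromosome 17, 48611377 to 48614939) went from 57.0 ± 0.837 to 7.68 ± 0.358 CPM. The other HOXB genes of this set were HOXB4 at -2.11, HOXB3 at -1.84 and HOXB9 at -1.62 on the log2 scale. HOXB3 shares 159 exonic bases with HOXB4 and 433 with HOXB6 on the same strand, so part of the reads of these genes cannot be assigned. PRKD3, a protein kinase D gene, fell 4.89-fold, and NAV3, a neuron navigator gene, fell 4.31-fold. The microtubule-associated gene MTUS1 fell from 131 ± 1.43 to 39.7 ± 0.472 CPM. The calcium sensor gene VSNL1 and the non-coding LINC01405 fell by 1.58 and by 1.54 on the log2 scale.

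**Figure D2:**
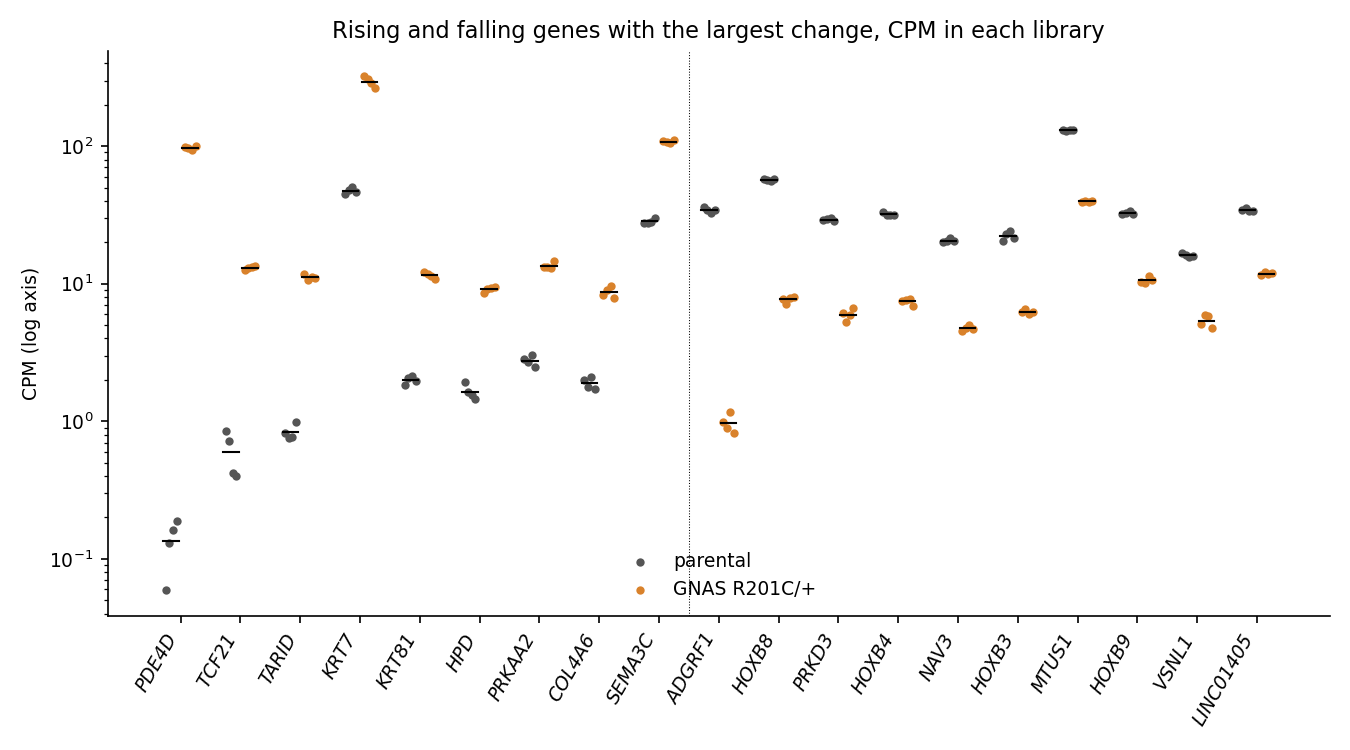
CPM (vertical log axis) in each of the 4 parental (grey) and 4 GNAS R201C/+ (orange) libraries for the rising genes (left) and the falling genes (right) reported among those with the largest change, with a black line at each group mean. The groups do not overlap for any of these genes, which the naming rule required.

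**Figure D3:**
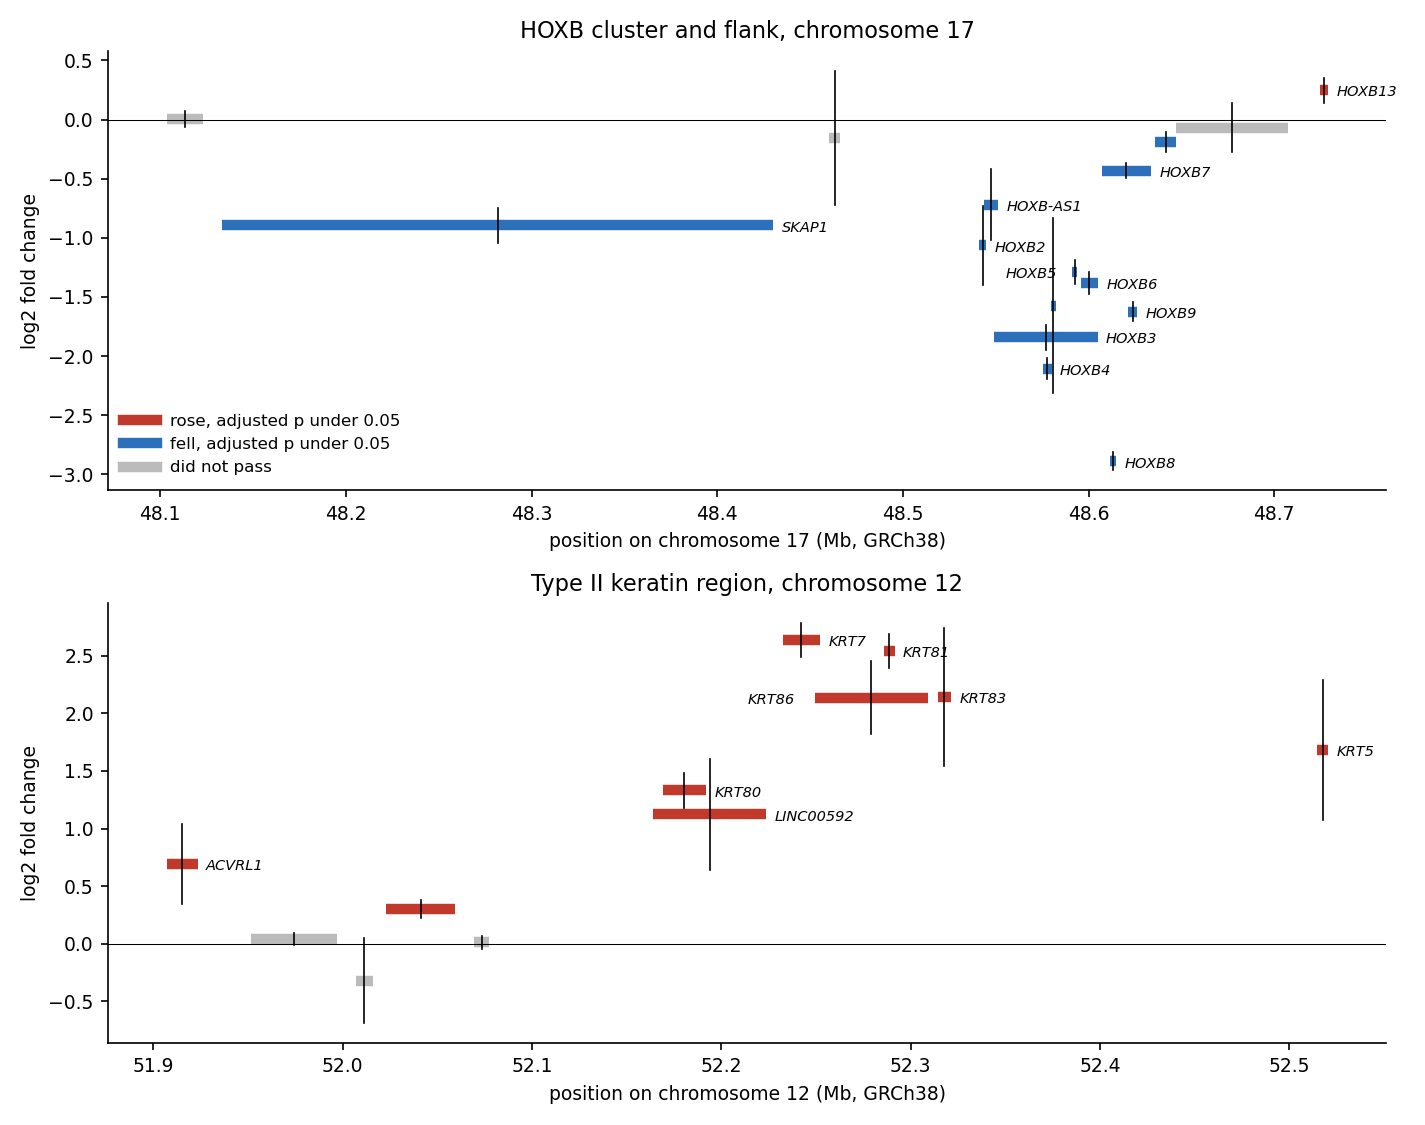
Log2 fold change (vertical axis) of tested genes by position in Mb of GRCh38 (horizontal axis) at the HOXB cluster on chromosome 17 and the type II keratin region on chromosome 12, both chosen after their values were seen, with bars for gene spans and thin black lines for approximate 95% intervals from the standard errors. The intervals assume a normal distribution and are too narrow where few degrees of freedom were left, as for KRT7 and KRT80. They may also be too narrow where a change is large and a group has few reads. HOXB2 to HOXB9 lie below 0 and HOXB13 at 0.25, and the keratin genes from KRT80 to KRT5 lie between 1.33 and 2.64.

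The question of a cAMP response was put to 3 lists. Of 24 tested cAMP and CREB response genes, 15 rose, 2 fell and 7 did not pass, and adjusted over the list alone 17 rose and 2 fell. The list's median log2 change was 0.34, higher than other genes by camera (adjusted p = 1.28e-17, and adjusted p = 0.00137 with an estimated correlation). NR4A2, an immediate early nuclear receptor, rose from 6.61 ± 0.120 to 11.9 ± 0.343 CPM. The EGF receptor ligand gene AREG rose from 191 ± 5.23 to 278 ± 3.87 CPM, and the phosphodiesterase gene PDE4B rose from 146 ± 1.76 to 222 ± 0.619 CPM. PDE4D belongs to this list too, and without it the list kept its call, with an adjusted p = 0.0350 with an estimated correlation. Without PDE3A, PDE4B and PDE4D this was 0.0422. TXNIP, another member, was listed at 0 in all 8 libraries. IRS2 fell by 0.48 and NFIL3 by 0.38 on the log2 scale, both named after their values were seen.

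Of 11 tested cAMP phosphodiesterases, 4 rose, 3 fell and 4 did not pass. The list passed camera (adjusted p = 5.26e-14, and adjusted p = 0.00192 with an estimated correlation), with a test pointing up and a mean log2 change of 0.98 but a median of -0.004. Here too the estimated correlation, -0.015, was below the preset 0.01. The call rested on PDE4D: without that gene, an alternative chosen after the data were seen, the camera adjusted p was 0.325 among 10 genes. Besides PDE4D and PDE4B, PDE8A rose by 0.21 on the log2 scale, and PDE3B fell by 0.36. Of 31 tested cAMP pathway components, 11 rose, 12 fell and 8 did not pass, and adjusted over the list alone 12 rose and 12 fell (camera adjusted p = 0.979). The median and mean log2 changes were -0.0004 and -0.01, while the test pointed up. The G protein genes GNAI2 and GNAI1 rose by 0.30 and 0.28 and the kinase subunit gene PRKACB by 0.26, while GNAL, a close relative of GNAS, fell by 0.55. GNAL shares 2261 exonic bases with MPPE1 on the opposite strand and is uncertain for that reason.

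Another 4 lists passed camera and did not pass with an estimated correlation. Of 22 tested epithelial junction genes, 16 rose, 2 fell and 4 did not pass (adjusted p = 2.48e-05, and adjusted p = 0.135 with an estimated correlation). The splicing regulator gene ESRP1, the E-cadherin gene CDH1 and the keratin gene KRT8 rose by 0.30, 0.33 and 0.25 on the log2 scale, and the tight junction gene CLDN3 rose from 9.68 ± 0.319 to 14.7 ± 1.24 CPM. Of 17 tested interferon response genes, 11 rose, 0 fell and 6 did not pass, and adjusted over the list alone 11 rose and 1 fell (adjusted p = 0.00616, and adjusted p = 0.135 with an estimated correlation). Among them IFIT1 rose from 4.15 ± 0.279 to 8.44 ± 1.08 CPM, ISG15 from 39.7 ± 1.72 to 55.7 ± 1.03 CPM and STAT2 from 40.2 ± 1.06 to 52.0 ± 0.516 CPM. Of 22 tested p53 targets, 11 rose, 2 fell and 9 did not pass (adjusted p = 0.0115, and adjusted p = 0.740 with an estimated correlation). FDXR, TP53I3 and RRM2B rose by 0.37, 0.71 and 0.26, and the exonuclease gene AEN fell by 0.23. SESN2, another member, was listed at 0 in all 8 libraries. Of 16 tested mesenchymal and EMT genes, 6 rose, 4 fell and 6 did not pass (adjusted p = 0.0316, and adjusted p = 0.392 with an estimated correlation). S100A4, a calcium-binding protein linked to motility, rose 1.98-fold to 465 ± 11.3 CPM, and the matrix genes COL6A1 and FN1 rose by 0.26 and 0.30. The intermediate filament gene VIM, itself a mesenchymal marker, fell by 0.69 on the log2 scale.

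**Figure D4:**
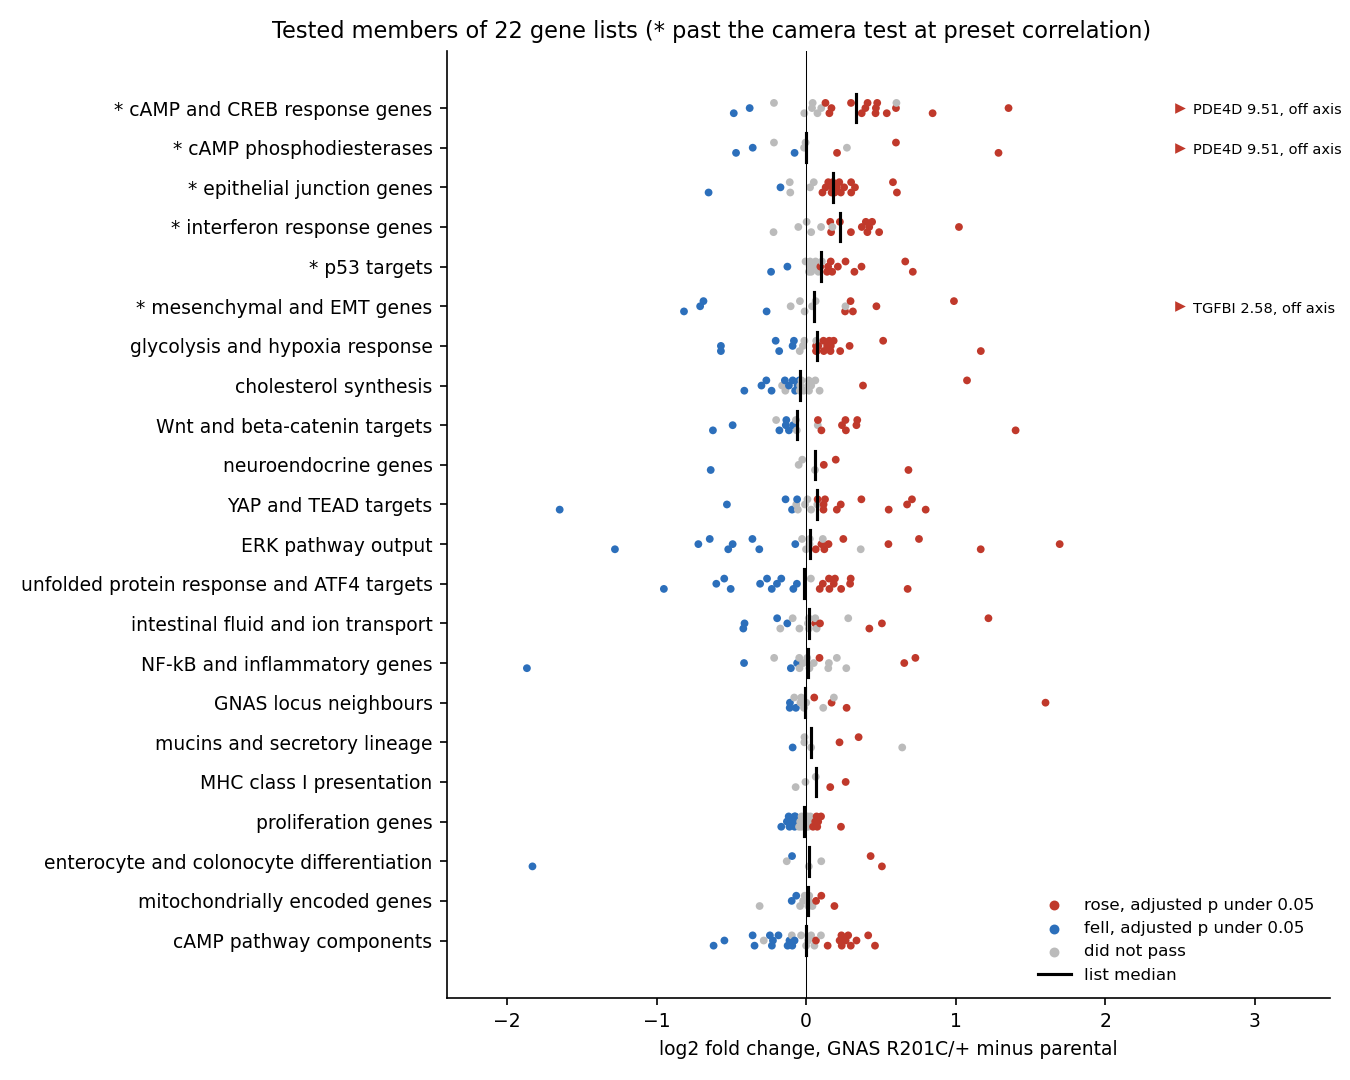
Log2 fold change (horizontal axis) of each tested member of 22 gene lists, with red and blue points for called genes, grey points for others and a black line at the list median. An asterisk marks the 6 lists past camera at the preset correlation, and arrowheads mark members beyond the axis, among them PDE4D at 9.51.

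The remaining lists did not pass camera, and their members moved in both directions or little. Of 19 tested Wnt and beta-catenin targets, 8 rose and 7 fell, with a median log2 change of -0.06, a mean of 0.05 and a test pointing up (adjusted p = 0.325). The secreted Wnt antagonist gene DKK1 rose from 167 ± 5.56 to 441 ± 16.8 CPM and its co-receptor gene KREMEN1 rose by 0.34, while MYC fell from 365 ± 7.52 to 260 ± 3.95 CPM and the Wnt receptor ligase gene RNF43 fell by 0.62. RNF43 is uncertain, since it shares 4326 exonic bases with AC004687.2 on the same strand. Of 23 ERK pathway output genes, 9 rose and 8 fell, with median 0.02, mean 0.04 and a test pointing down (adjusted p = 0.595). The phosphatase gene DUSP4 rose from 106 ± 2.37 to 239 ± 7.91 CPM, DUSP5 fell from 160 ± 1.61 to 102 ± 2.28 CPM, and EMP1 fell from 142 ± 3.81 to 58.6 ± 3.17 CPM. Of 22 YAP and TEAD targets, 11 rose and 5 fell, or 6 fell when adjusted over the list alone (adjusted p = 0.582). Among these NUAK2 rose by 0.80, NT5E by 0.37 and CYR61 by 0.23, and ASAP1 fell by 0.53. Of 18 NF-kB and inflammatory genes, 3 rose and 4 fell, with median 0.01, mean -0.02 and a test pointing up (adjusted p = 0.595). NFKBIA and ICAM1 rose by 0.66 and 0.73, and LCN2 and TNFAIP3 fell by 1.87 and 0.42 on the log2 scale.

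Metabolic and growth lists were mixed. Of 25 glycolysis and hypoxia response genes, 15 rose, 6 fell and 4 did not pass (camera adjusted p = 0.0731, and adjusted p = 0.656 with an estimated correlation). The list passed without parental replicate 1 (adjusted p = 0.0421) and without GNAS R201C/+ replicate 4 (adjusted p = 0.0430), in a range of 0.0421 to 0.128 over the 12 alternatives tested at the preset correlation. The glucose transporter gene SLC2A1 rose from 237 ± 3.01 to 532 ± 15.9 CPM, PKM and PGK1 rose by 0.23 and 0.18, and the peptide hormone gene ADM fell by 0.57. Of 24 cholesterol synthesis genes, 2 rose and 10 fell (adjusted p = 0.325). HMGCS1, SQLE and INSIG1 fell by 0.41, 0.30 and 0.27. Of 22 unfolded protein response and ATF4 targets, 10 rose and 11 fell (adjusted p = 0.595). The 4 members that the naming rule took all fell: the cystine transporter gene SLC7A11 by 0.60, TRIB3 by 0.50, PSAT1 by 0.26 and ATF4 by 0.23. Among the 10 that rose, DDIT4 rose by 0.68, CRELD2 by 0.30 and XBP1 by 0.23, all named after their values were seen. SESN2 and VLDLR, the untested members of that list, were listed at 0 in all 8 libraries. Of 28 proliferation genes, 7 rose and 9 fell, or 10 fell when adjusted over the list alone (adjusted p = 0.595). CCNE2, which shares 1629 exonic bases with INTS8 on the opposite strand, rose by 0.23, and BUB1B, MCM7 and MCM4 fell by 0.17, 0.12 and 0.11. Of 13 mitochondrially encoded genes, 3 rose and 2 fell, with median 0.01, mean -0.007 and a test pointing up (adjusted p = 0.716). MT-ND3 and MT-ND2 rose by 0.19 and 0.10, and MT-ATP8 and MT-CO1 fell by 0.10 and 0.07. MT-CO1 did not pass without parental replicate 2 (adjusted p = 0.113) or without GNAS R201C/+ replicate 2 (adjusted p = 0.0543).

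Intestinal differentiation genes were thinly represented among the tested genes. Of 30 mucin and secretory lineage genes, 7 were tested, of which 2 rose, 1 fell and 4 did not pass (camera adjusted p = 0.595). The glycosyltransferase gene GALNT12 rose by 0.22 and MUC1 by 0.35, and MUC3A fell by 0.09. The MUC1 call ended without parental replicate 3 or 4 (adjusted p = 0.0741 and 0.0777) and without GNAS R201C/+ replicate 2 or 3 (0.0541 and 0.0620). The MUC3A call ended without parental replicate 3 or 4 (0.0823 and 0.0578) and without GNAS R201C/+ replicate 1 or 2 (0.113 and 0.0923), and it did not pass with DESeq2 (0.0700) or with no filter on low counts (0.0598). MUC2 had 0 or 1 read per library, and MUC5AC, MUC4 and MUC6 were listed at 0 in all 8. Some genes that every cell uses were also listed at 0, so these values do not show that the mucin genes were silent. Of 7 tested enterocyte and colonocyte genes, 2 rose and 2 fell, or 3 rose when adjusted over the list alone, with median 0.02, mean -0.14 and a test pointing up (adjusted p = 0.595). The carbonic anhydrase gene CA2 rose from 42.4 ± 0.807 to 60.1 ± 1.69 CPM and DPP4 by 0.43, and the intestinal regulator gene HNF4A fell from 2.84 ± 0.234 to 0.796 ± 0.0882 CPM. CDX2 fell by 0.09, a call that ended without parental replicate 3 or 4 (adjusted p = 0.105 and 0.0670) and without GNAS R201C/+ replicate 1, 2 or 3 (0.0756, 0.130 and 0.0540). CDX2 did not pass either with DESeq2 (0.0943), with no filter on low counts (0.0918) or with the replicate number as a block (0.0502). Of 18 fluid and ion transport genes, 5 rose and 4 fell (adjusted p = 0.595). The water channel gene AQP3 rose 2.33-fold to 25.7 ± 2.14 CPM, and the transporter gene SLC4A7 and the carbonic anhydrase gene CA12 fell by 0.41 and 0.42. Of 7 tested neuroendocrine genes, 3 rose and 1 fell (adjusted p = 0.474), with SCG2, CPE and ENO2 up by 0.68, 0.20 and 0.12. CCK fell by 0.64, a call that ended without parental replicate 2, 3 or 4 (adjusted p = 0.0612, 0.129 and 0.119) and without GNAS R201C/+ replicate 1, 2 or 3 (0.0827, 0.0866 and 0.0864). CCK did not pass with DESeq2 (0.0790) or limma-voom (0.0652) either. Of 5 tested MHC class I presentation genes, 2 rose and 0 fell (adjusted p = 0.595): B2M rose by 0.16 and ERAP1 by 0.26. The other 10 members of that list, HLA-B and HLA-C among them, had at most 20 reads in any library. Most of them lie in a region of chromosome 6 where nearly all protein-coding genes were listed at or near 0, so their levels are not known.

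Most markers of other cell types had too few reads to be tested. Of 16 leukocyte, 14 fibroblast and 12 endothelial markers, 4, 4 and 2 were tested, too few for a test of the list. COL1A1 and FBLN1, fibroblast markers named after their values were seen, were well counted, with log2 changes of -0.02 (adjusted p = 0.770) and 0.0005 (adjusted p = 0.992). CORO1A fell from 4.14 ± 0.159 to 3.03 ± 0.404 CPM, and no other marker passed. The fibroblast markers PDGFRB and TWIST1 had log2 changes of 0.26 (adjusted p = 0.345) and -0.10 (adjusted p = 0.527). The endothelial markers ESAM and VWF had changes of -0.13 (adjusted p = 0.119) and 0.18 (adjusted p = 0.563). Counts adjusted over the list alone were equal to those over all tested genes for 19 of the 25 lists. Of 23 chromosomes, 0 passed camera, 0 had an unadjusted p under 0.05 and 0 passed with an estimated correlation, while fry, which asks only whether genes move on balance one way, called 16. Chromosome medians lay between -0.04 and 0.02.

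The first principal component held 55.8% of the variance and separated the groups. Of 15751 tested genes, 6549 had every library of one group above every library of the other, which chance alone gives for 2.86% of genes. Of the calls, 5059 were under 1.2-fold. With a test against a 1.5-fold change, 256 genes passed, 138 higher and 118 lower. The running numbers in the labels place all parental libraries before all GNAS R201C/+ libraries, so the order of preparation or sequencing and the genotype cannot be told apart.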

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

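The test of library order was chosen after the results had been seen, as was the count of splits for lists with an estimated correlation. The GC, gene length and other split tests were planned.

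Single libraries stood apart from the other 3 of their group for 11 of 216 sets of 4 values examined, against 10.8 expected by chance at the level used. Among parental libraries, replicate 1 was apart for GALNT12 (37.3 CPM), HMGCS1 (122 CPM) and TFAP2C (9.96 CPM). Replicate 2 was apart for B2M (18.8 CPM), replicate 3 for HOXB9 (33.8 CPM) and SCG2 (6.20 CPM), and replicate 4 for LCN2 (0.939 CPM). Among GNAS R201C/+ libraries, replicate 1 was apart for HNF4A (0.664 CPM), replicate 3 for RNF43 (19.6 CPM), and replicate 4 for CLDN3 (16.6 CPM) and CCK (0.513 CPM). None of the quality measures of a library (total counts, genes detected, and the shares of mitochondrial, ribosomal protein and most abundant genes) stood apart in this way.

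Of all tested genes, 48.1% were called, most of them with small changes. The fitted common coefficient of variation between libraries of a group, beyond counting error, was 2.23%. With so little spread, small differences can pass the test. Of the 35 ways to divide the 8 libraries into 4 and 4, only the real one gave as many as 7577 genes. The highest of the others gave 1. The same held for the 242 genes changed at least 2-fold (1 of 35 splits, highest other 1). A share of 1 in 35 is the lowest this test can give. Every other split mixes the groups, so the group difference adds to the spread within each side. Few calls are likely there whatever the cause, so the split count does not show how the 7577 calls arose. Removing a GC trend from each library left 7605 genes called, of which 6821 were among the original calls with the same sign, and removing a gene length trend left 7544, of which 6901 were. These counts argue against either trend as the whole cause. Library order or handling also stays open, because 0 libraries of one group had a running number inside the range of the other. So do clonal differences between the derivative and its parent, which the design does not separate from the GNAS genotype.

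Set results were less secure than gene results. In 3 of the 35 splits at least 6 gene lists passed camera at the preset correlation, and the highest of the other splits also gave 6, so chance division is not excluded for the number of lists. With an estimated correlation 2 lists passed in the real division and 0 in any other (1 of 35 splits). That count has the same limits as the split counts for genes. The cAMP and CREB response list passed at the preset correlation in 0 of the 18 splits that mix the groups evenly and in 16 of the 16 that keep 3 libraries of a group together. No chromosome passed in the real division or in any other (35 of 35 splits, highest other 0), so there was no chromosome result to weigh.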

How the results depend on the processing

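The alternatives without PDE4D and without PDE3A, PDE4B and PDE4D were chosen after the results had been seen, and the others were planned. The number of called genes was between 6633 (DESeq2) and 7611 (library totals only) with all 8 libraries, and between 6905 and 7442 with each library left out in turn. No gene called in both changed sign in any of these. Another scaling moved the share of calls that were higher from 50.1% to 47.7% at most. The number of genes changed at least 2-fold was 477 with no filter on low counts and 131 with at least 1 CPM in 4 libraries, where fewer low genes are tested, and 220 to 232 of the 242 calls were kept with each library left out. The variance on the first principal component was 77.9% with the 1 CPM filter and 74.5% over the 500 most variable genes, both of which use fewer genes; the cause was not tested further. The number of lists called was 2 with an estimated correlation and 16 with fry, and fry called 16 chromosomes; fry does not compare a list with other genes. The GNAS log2 fold change kept its direction and call in all 16 alternatives, between 0.06 and 0.09, with adjusted p between 0.000168 and 0.0341.

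Among 105 other genes that the naming rule took, 1647 of 1676 alternative values kept direction and side of the threshold. The 28 that lost their call belonged to MUC1, MUC3A, CDX2, CCK and MT-CO1, whose changes lie near the threshold. TWIST1, which was not called, changed sign without GNAS R201C/+ replicate 1 (0.0131), and its log2 change lay between -0.18 and 0.0131 with each library left out. The cause was not tested. The glycolysis and hypoxia list passed camera at the preset correlation without parental replicate 1 (adjusted p = 0.0421) and without GNAS R201C/+ replicate 4 (adjusted p = 0.0430), while with all libraries it had an adjusted p = 0.656 with an estimated correlation. Without PDE4D the cAMP and CREB response list had an adjusted p = 0.0350 with an estimated correlation, and without PDE3A, PDE4B and PDE4D an adjusted p = 0.0422. With the replicate block 7413 genes were called and 240 changed at least 2-fold, and the only named gene to lose its call was CDX2. Same-numbered libraries did not deviate together (r between -0.05 and 0.05, against -0.10 and 0.09 for other pairings across groups). The numbers thus gave no sign of a pairing, which does not exclude that libraries were grown or prepared in matched sets. Depth limits the genes with fewest reads: 3 counts in a library correspond to 0.0588 to 0.0704 CPM.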

Other observations

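The tests of neighbouring genes against chance placement, family copies and copy number, of HOX genes of other clusters, and of genes listed at 0 were chosen after the results had been seen. The test without overlapping genes was planned. All genes and families in this part beyond those of the naming rule were picked after their values were seen.

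Members of several gene families, none of them a list fixed beforehand or tested for enrichment, changed in level. Of 9 tested HOXB genes 8 fell, HOXB6 by a log2 change of -1.38 to 13.8 ± 0.787 CPM and HOXB5 from 18.5 ± 0.853 to 7.55 ± 0.434 CPM among them, and HOXB13 rose from 12.8 ± 0.382 to 15.2 ± 1.51 CPM. HOXB6 shares 433 exonic bases with HOXB3 on the same strand and is uncertain for that reason. SKAP1, next to the cluster, fell from 9.17 ± 0.907 to 4.94 ± 0.505 CPM. Of 19 tested genes with histone names from the replication clusters, 13 rose, 0 fell and 6 did not pass, though near-identical copies make single histone genes uncertain. HIST1H2AC went from 3.26 ± 0.113 to 7.37 ± 0.430 CPM and HIST1H1C from 5.46 ± 0.571 to 9.04 ± 0.339 CPM. Many of the others were low, such as HIST1H4I, which went from 0.161 ± 0.0634 to 0.297 ± 0.0759 CPM. Of the basement membrane collagens, COL4A5 rose from 22.2 ± 0.122 to 56.5 ± 2.29 CPM, and the head-to-head neighbour COL4A6 rose with it. The class of secreted semaphorins split: SEMA3A rose from 3.61 ± 0.230 to 9.93 ± 0.225 CPM and SEMA3B from 41.6 ± 1.88 to 71.2 ± 1.94 CPM, while SEMA3E fell by 1.15 on the log2 scale. The HOXB and histone counts were the same with TMM, DESeq2 size factors, upper-quartile scaling and library totals only.

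MAP6 and UNC5C were present in 1 group and listed at 0 in all 4 libraries of the other. MAP6, a microtubule-stabilising protein gene, had 18 to 37 reads per parental library and 0 in every GNAS R201C/+ library, at least 36.5-fold lower against a floor of 3 counts over the group. UNC5C, a netrin receptor gene, had 12 to 15 reads per GNAS R201C/+ library and 0 in every parental library, at least 17.1-fold higher against the same kind of floor.

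Genes changed at least 2-fold often sat next to each other: among 15591 tested genes in chromosome order, 30 adjacent pairs changed in one direction, against 1.80 on average and 8 at most when calls were permuted (one-sided permutation p = 1e-04 against chance placement, the smallest that 10000 permutations can give). Among genes whose spans do not overlap there were 22 pairs (permutation p = 1e-04, the same minimum), and with 1 gene also kept of neighbouring protein-coding genes with the same name stem there were 12, the non-coding neighbours AL024497.1 and AL024497.2 still among them (mean 1.66, at most 8, permutation p = 1e-04), so shared reads are not the whole cause. Tested genes within 1 Mb that were not called at 2-fold or more moved by a median of 0.0398 in the direction of the run (95% bootstrap interval 0.01 to 0.11, 19 runs). This is far below the runs themselves, so these flanking genes showed no shift of the size of the runs. Leaving out the genes changed at least 2-fold favours a small median, and a change confined to a run would not show in it. A copy number change at single runs is therefore not excluded. Tested HOXA, HOXC and HOXD genes had a median log2 change of -0.0486 (interval -0.17 to 0.01), which argues against a shift of these genes as a pool. The 3 tested HOXD genes alone had a median of -0.371 and none was called, so that cluster is undecided. The design does not separate the genotype from clonal differences, and no biological explanation was tested.

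Some genes that no cell lives without were listed at or near 0 in every library. Of 77 core ribosomal protein genes, 68 had over 1000 reads in every library, and 5, RPL7A and RPS9 among them, had at most 20, which argues against loss of the genes from these cells. On chromosome 6 between 29000000 and 33000000, 152 of 153 protein-coding genes, or 99.3%, had at most 20 reads in every library, against 52.6% within 5 Mb on either side. The tubulin gene TUBB and the splicing helicase gene DDX39B were listed at 0 there, and outside it the RNA polymerase subunit gene POLR2A and the thioredoxin-interacting protein gene TXNIP were listed at 0 as well. These values are in line with whole regions left uncounted in the processing, possibly because reads that also match alternate copies of a region were dropped, which could not be tested without those sequences.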
